A study of Mus musculus with 13 samples.

How the data were processed

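RNA was measured in testicular germ cells of 8-week-old C57BL/6 mice. Per the labels' protocols, total RNA was extracted, ribosomal RNA was depleted and directional libraries were made. Values of 2 of the 13 samples were analysed, the spermatogonial samples titled KIT_AGSC and THY1_AGSC (KIT and THY1 below), with 1 library each, and the other 11 were not analysed here. The deposited tables hold 1 gene symbol and 1 decimal value per row, for 20662 symbols in the same order, and their headers name no unit. The values were taken as FPKM, as the authors' use of Cufflinks 2.1.1 implies per the submitters' processing notes, because they are not whole numbers and their sums differ (1518740 and 804044). These notes also name TopHat 1.4.1, CASAVA and the mouse build mm9, without roles. The gene annotation, the treatment of reads with several alignments and any filter are not given in the sources used here. Reads that match several places could be lost from genes with many near-identical copies, and FPKM is divided by a total that includes very abundant noncoding RNA, so a library rich in such RNA has lower values elsewhere.

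Each table was assigned to its sample as recorded in the series, and each sample to a group by its title. The value column of the sample titled KIT is headed Thy1 and that of the sample titled THY1 is headed Kit. Titles were followed throughout, and the libraries are called the library labelled KIT and the library labelled THY1. Coordinates were not used, because the annotation at hand (GENCODE M21) is on another build than mm9. It gave transcript lengths and the chromosome of each symbol only, and 18395 symbols (89.0%) matched it.

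Differences were taken on the log2(FPKM + 1) scale as labelled KIT minus labelled THY1, which understates the change of low genes. The pseudocount was 1 and genes counted where the larger value was at least 1 FPKM. With 1 library per group no test between groups is possible, so genes were counted by a fixed size of 2-fold. Folds are not given where a library lists 0. Lists of genes (29 by members, and 3 by symbol or chromosome: cytosolic ribosomal proteins, replication-dependent histones and X-linked genes) were compared with 10000 random lists of the same size drawn from the same 20 bins of mean log2 expression, for lists with at least 5 usable members. The percentile describes these libraries and is not a p-value. Lists outside the central 95% of random lists are called outside the random range, a bound set after the values had been seen. On simulated differences over 15573 genes, 7 of 100 lists of 20 unchanged genes fell outside that range. For lists shifted by 0.5, 1, 2 and 3 on the log2 scale, 5, 35, 53 and 100 of 100 lay above it. All lists of a given shift were drawn from the same small set of shifted genes, so they share members and are not independent.

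The gene lists, the counting rule, the naming rule and most alternatives were fixed before the data were examined. Named genes are Kit and Thy1, the 12 genes with the largest difference in each direction with a larger value of at least 5 FPKM, the 5 genes with the highest mean (both leaving out predicted genes, RIKEN clones, small RNAs and pseudogenes), and per list up to 4 members with the largest difference and 2 with the highest mean. Exceptions are marked as chosen after their values were seen, and some genes that the rule names are not reported here. Other settings chosen before the data were examined were a pseudocount of 0.1, scaling to a median ratio of 1 or to the same upper quartile, no filter or a minimum of 5 FPKM, and random lists not matched on expression. Added after seeing the data were scaling to the sum without Rpph1, genes above 0 in both libraries (with the minimum of 1 FPKM kept for counts and lists), and a minimum of 30 FPKM.

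Depth per library is unknown. Among genes with a single annotated transcript over 1000 bases, FPKM multiplied by length at percentile 5 of values above 0 served as the worth of 1 fragment, and the ratio between the libraries was 6.41 (6.46 at percentile 2 and 5.98 at percentile 10). Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.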

Results

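The series profiled RNA of germ cells from the testes of 8-week-old C57BL/6 mice by ribosomal-RNA-depleted, directional RNA-seq. Its 13 samples comprise 5 of spermatocytes, 5 of spermatids, 1 of mature sperm and 2 of spermatogonia, the mitotic germ cells that precede meiosis. The 2 spermatogonial samples, titled KIT_AGSC and THY1_AGSC, are named for surface antigens and are called KIT and THY1 here: KIT, the receptor for stem cell factor carried by differentiating spermatogonia, and THY1, an antigen used to enrich undifferentiated spermatogonia. Values per gene were analysed here for these 2 libraries only, and the other 11 samples were not analysed here. With 1 library per group there are no replicates, so every difference below compares 2 libraries, has no replicate check and carries no p-value. Both tables list the same 20662 gene symbols, with values taken as FPKM. Total counts are unknown, but a low-end measure of depth (FPKM multiplied by transcript length, at percentile 5 of genes above 0) was 2735 in the library labelled KIT and 427 in the library labelled THY1. The value of a single fragment was thus about 6.41 times larger in the former, so its relative depth was lower. Of the listed genes, 6866 (33.2%) were at exactly 0 in the library labelled KIT and 5006 (24.2%) in the library labelled THY1. Genes that nearly every cell uses, singled out here after their values were seen, were among them. Ppia was listed at 0 in both libraries, Gapdh at 3.12 and 0 FPKM, and Hprt at 0 and 56.2 FPKM (labelled KIT first). A value of 0 is therefore given only as listed at 0.

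The first comparison checked each library against its name, and the antigen transcripts ran opposite to the labels. Kit was listed at 0 in the library labelled KIT and at 36.7 FPKM in the library labelled THY1. Thy1 stood at 78.8 FPKM in the library labelled KIT and at 0.723 FPKM in the library labelled THY1, a ratio of 109. The tables themselves also carry the other name, since the value column of the sample titled KIT is headed Thy1 and that of the sample titled THY1 is headed Kit. Every direction below follows the sample titles and is written as the library labelled KIT or THY1. All directions would turn if the titles were exchanged.

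**Figure D1:**
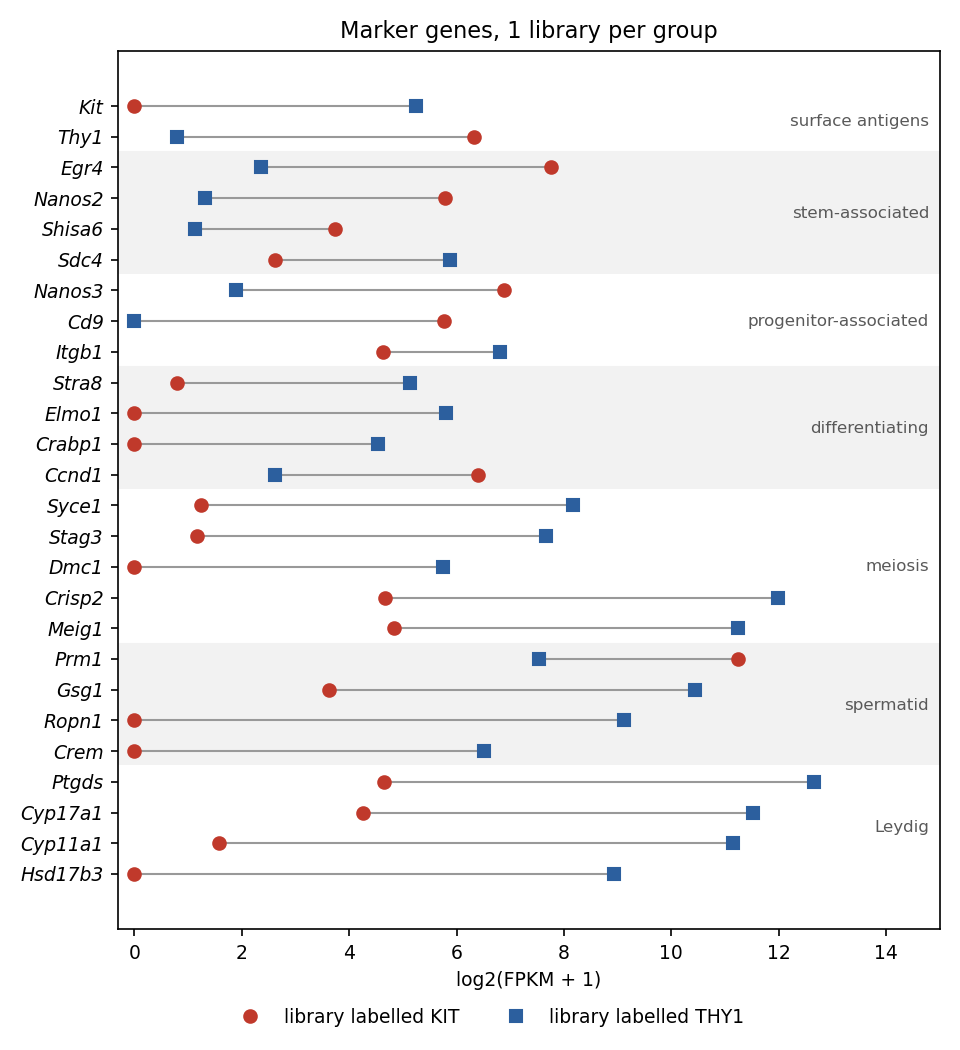
Expression of named marker genes in the library labelled KIT (red circles) and the library labelled THY1 (blue squares), as log2(FPKM + 1) with 1 library each and no error bars. Kit lies at 0 in the library labelled KIT and Thy1 is higher there, while Stra8, Stag3 and Cyp11a1 are higher in the library labelled THY1.

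The 2 profiles differed widely. Among 15573 genes with a larger value of at least 1 FPKM, 6147 were at least 2-fold higher in the library labelled KIT and 6408 were at least 2-fold higher in the library labelled THY1 on the log2(FPKM + 1) scale. Together these made up 80.6% of the genes, and 3018 lay within 2-fold. The minimum of 1 FPKM is easier to pass in the library labelled KIT, where 1 fragment is worth more. Some genes counted as higher there may therefore rest on few fragments, and these counts include such sampling differences. Of the former, 1038 were listed at 0 in the library labelled THY1, and of the latter, 2233 were listed at 0 in the library labelled KIT. Across all genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.42 and Spearman's rho was 0.48. Among genes with a larger value of at least 1 FPKM, r was 0.15. A single noncoding RNA, Rpph1 (the RNA component of RNase P), made up 71.8% of the summed FPKM in the library labelled KIT and 37.9% in the library labelled THY1, at about 1090800 and 304359 FPKM. Leaving out predicted genes and RIKEN clones, the other genes with the highest mean values were Ptgds (24.1 and 6463 FPKM, labelled KIT first), Acat3 (4912 and 1335), Crisp2 (24.4 and 4082) and Spa17 (2496 and 1152).

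**Figure D2:**
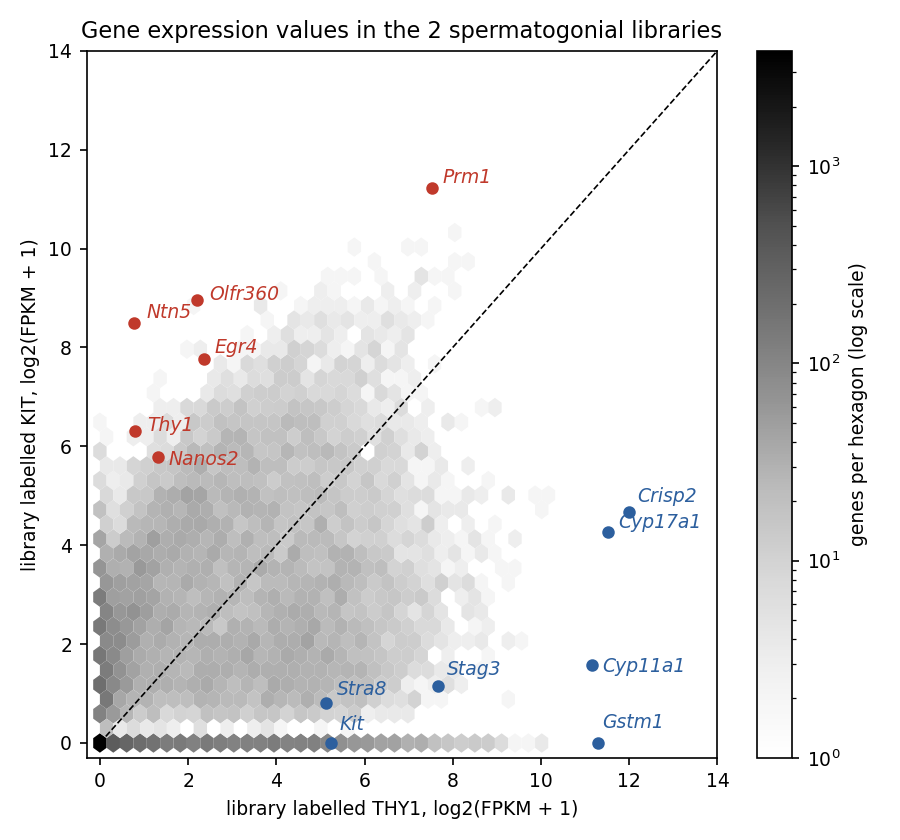
All genes by log2(FPKM + 1) in the library labelled THY1 (horizontal) and the library labelled KIT (vertical), shaded by the number of genes per hexagon on a log scale. Named genes are red where higher in the library labelled KIT and blue where higher in the library labelled THY1, the dashed line marks equal values, and Rpph1 lies beyond both axes. The cloud is broad (r = 0.42), with a row of genes listed at 0 along each axis.

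Of the 12 named genes with the largest differences toward the library labelled THY1, 11 were listed at 0 in the other library. The glutathione transferase Gstm1 was at 2512 FPKM, the epoxide hydrolase Ephx1 at 1225, the annexin Anxa2 at 1066, the apolipoprotein Apoc1 at 1037 and the respiratory subunit Cox4i1 at 985 in the library labelled THY1, and each was listed at 0 in the library labelled KIT. The same held for Mael, of the piRNA pathway (889 FPKM), Dnajc15 (724), Ndufa1 (632), Atp5e (607), Gsta4 (582) and Arpc3 (568). Cyp11a1, which makes pregnenolone from cholesterol, was at 2272 FPKM against 1.97. Toward the library labelled KIT, the list was led by Ntn5, a netrin-family gene, at 362 FPKM against 0.721. It held 4 olfactory receptor genes, Olfr360 (499 against 3.62 FPKM), Olfr1286 (188 against 1.39), Olfr420 (142 against 0.918) and Olfr981 (176 against 1.52). The beta-defensin Defb35 was at 802 FPKM against 7.31, the kinase Srms at 419 against 3.60 and Dpm2 at 621 against 5.91. Hist1h4b (149 FPKM), Rps28 (83.8), Cck (78.6) and Tbxa2r (69.3) were listed at 0 in the library labelled THY1.

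Gene lists were then compared, each as the median difference of its members against 10000 random lists of the same size and mean expression. Of 30 lists with at least 5 usable members, 11 lay below the central 95% of random lists (higher in the library labelled THY1), 2 lay above it (higher in the library labelled KIT) and 17 lay inside. Chance would put 1.5 lists outside if genes were independent, which genes of a list are not. Medians are given as labelled KIT minus labelled THY1.

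**Figure D3:**
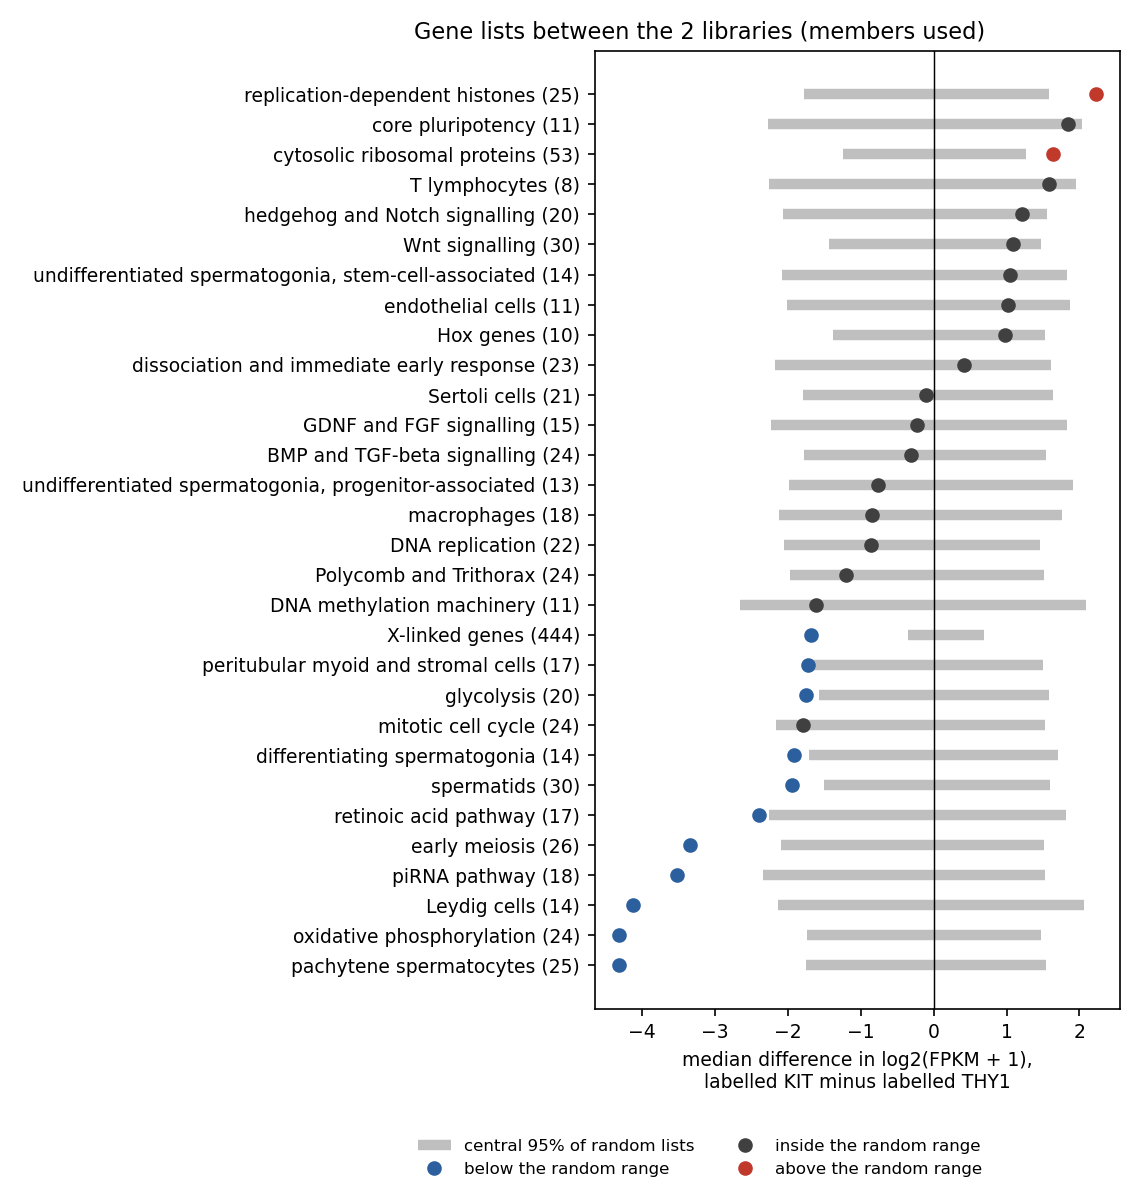
Median difference in log2(FPKM + 1) of each gene list between the 2 libraries (points, with the number of members used in parentheses) and the central 95% of 10000 random lists matched on size and mean expression (grey bars). Pachytene spermatocyte, oxidative phosphorylation and Leydig cell lists lie furthest to the left (-4.32, -4.31 and -4.12), and replication-dependent histones furthest to the right (2.23).

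Spermatogonial genes did not all differ in one direction. Of 14 usable genes tied to stem cell spermatogonia, 7 were at least 2-fold higher in the library labelled KIT, whose value column is headed Thy1, and 4 in the library labelled THY1. Egr4, a zinc-finger factor, stood at 217 FPKM in the library labelled KIT against 4.11, Nanos2, an RNA-binding factor that maintains stem spermatogonia, at 54.1 against 1.49, and Shisa6 at 12.4 against 1.17. The syndecan Sdc4 went the other way at 5.18 against 57.8 FPKM, and Tspan8 was similar at 73.5 and 54.5. The list's median of 1.05 lay at percentile 80 of random lists, inside their central range of -2.08 to 1.82. The progenitor list (13 usable genes, 4 higher in the library labelled KIT and 6 in the other) had a median of -0.76 at percentile 24.3. With the library labelled KIT first, it held Nanos3 at 118 against 2.74 FPKM, Cd9 at 53.5 FPKM against a listed 0, Itgb1 at 23.9 against 111, and Gpr125 and Ddit4 at a listed 0 against 11.7 and 9.95. Chosen after their values were seen, the GDNF receptor Gfra1 was at 3.91 FPKM in the library labelled KIT against 0.102, Id4 at 3.75 against 0.936, and Zbtb16 was listed at 0 in both libraries. Also chosen so, Epha2 was at 4.89 against 12.4 FPKM, and Etv5 and Pvr were at a listed 0 against 2.95 and 3.44. Of the 20 measured stem-cell-associated genes, 7 were listed at 0 in the library labelled KIT and 3 in the other. Values as low as that of Gfra1 may rest on few fragments in the library labelled KIT.

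Genes of differentiating spermatogonia were higher in the library labelled THY1, whose value column is headed Kit. Of 14, 9 were at least 2-fold higher there and 2 in the library labelled KIT, with a median of -1.92 at percentile 1.39. Stra8, the retinoic-acid-induced gatekeeper of meiosis, was at 34.1 FPKM in the library labelled THY1 against 0.743. Elmo1 (54.9 FPKM) and the retinoid-binding Crabp1 (22.2 FPKM) were listed at 0 in the library labelled KIT, whereas the cyclin Ccnd1 was at 83.6 FPKM there against 5.18. In the library labelled KIT 8 members were listed at 0. Over the 5 members above 0 in both libraries, an alternative added after seeing the data, the median was 0.082 at percentile 31.6. The list also lay inside the random range with a minimum of 5 FPKM and against random lists not matched on expression.

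Meiotic genes were higher in the library labelled THY1, whose value column is headed Kit and whose labelled cell type is spermatogonia. In the early meiosis list 23 of 26 genes were at least 2-fold higher there and 1 in the library labelled KIT, with a median of -3.34 at percentile 0.01. The synaptonemal complex gene Syce1 was at 285 FPKM against 1.37, the meiotic cohesin Stag3 at 203 against 1.24, and Sycp3 at 286 against 111. The recombinase Dmc1 (52.6 FPKM) and Tex11 (47.5 FPKM) were listed at 0 in the library labelled KIT. Of 25 pachytene spermatocyte genes, 18 were at least 2-fold higher in the library labelled THY1 and 5 in the other, with a median of -4.32 below all random lists. Crisp2 was at 4082 against 24.4 FPKM, Meig1 at 2410 against 27.7, and Adam2 (242 FPKM) and Tex101 (65.0 FPKM) were listed at 0 in the library labelled KIT. The piRNA pathway, which silences transposons in germ cells, followed with 12 of 18 genes higher in the library labelled THY1 and 3 in the other (median -3.52, percentile 0.08). Mael (889 FPKM), Gtsf1 (556 FPKM) and Ddx25 (126 FPKM) were listed at 0 in the library labelled KIT, and the germ cell helicase Ddx4 was at 140 against 1.77 FPKM. Without genes listed at 0 the early meiosis median was -1.64 (percentile 3.58) and the piRNA median -1.62 (percentile 16.2), both inside the random range, and the pachytene median was -2.54 (percentile 0.22), outside it.

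Spermatid genes split. Of 30, 18 were at least 2-fold higher in the library labelled THY1 and 12 in the library labelled KIT, and none lay within 2-fold (median -1.94, percentile 0.76). Gsg1 was at 1388 FPKM in the library labelled THY1 against 11.3, and Ropn1 (552 FPKM), the transcription factor Crem (89.7 FPKM) and the acrosomal Spaca1 (72.4 FPKM) were listed at 0 in the library labelled KIT. The sperm DNA-packaging protamine Prm1 was the reverse, at 2406 FPKM in the library labelled KIT against 184. Chosen after their values were seen, and with the library labelled KIT first, Prm2 was at 1110 against 148 FPKM, Tnp1 at 732 against 159 and Tnp2 at 575 against 131. In the other direction, Smcp was at 43.5 against 132 FPKM and Gapdhs at 26.5 against 189.

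Markers of somatic testis cells were present in both libraries. Genes of Leydig cells, which make testosterone, were higher in the library labelled THY1, whose value column is headed Kit, for 10 of 14 genes and in the library labelled KIT for 2 (median -4.12, percentile 0.01). Prostaglandin D synthase Ptgds was at 6463 FPKM against 24.1, Cyp17a1 at 2945 against 18.1 and Cyp11a1 at 2272 against 1.97. Hsd17b3 (488 FPKM) and Hsd3b6 (419 FPKM) were listed at 0 in the library labelled KIT. The median Leydig gene stood at 81.9 FPKM in the library labelled THY1 and at 14.75 FPKM in the library labelled KIT, and without genes listed at 0 the median difference was -2.95 (percentile 0.30). Peritubular and stromal genes were split with 10 of 17 higher in the library labelled THY1 and 7 in the other (median -1.72, percentile 2.35), including Sparc at 680 against 15.1 FPKM, Vcam1 at 634 against 0.7495 and Col3a1 at 37.7 against 0.546. Dcn, a matrix proteoglycan at 91.9 FPKM, was listed at 0 in the library labelled KIT. Chosen after their values were seen, Tagln (155 against 47.2 FPKM), Mylk (37.1 against 6.10) and Cnn1 (16.9 against 0.272) were among the 7 higher in the library labelled KIT. This list lay inside the random range with a pseudocount of 0.1, after scaling to the upper quartile or to the sum without Rpph1, with no filter, and against unmatched random lists.

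The other somatic lists did not stand apart from random lists. Sertoli genes had a median of -0.10 (percentile 41.4), with Clu at 848 FPKM in the library labelled THY1 against 1.62, Vim at 375 against a listed 0, Ctsl at 19.8 against 1.59, and Defb36 at 13.1 FPKM in the library labelled KIT against a listed 0. Macrophage genes had a median of -0.84 (percentile 22.2), with Aif1 at 880 FPKM in the library labelled THY1 against 24.5, Mrc1 at 23.7 against 1.82, and the complement genes C1qb (119 against 16.0 FPKM) and C1qc (48.3 FPKM against a listed 0) larger in the library labelled KIT. T lymphocytes, which carry THY1, had a median of 1.58 (percentile 91.8), with Cd5 at 27.5 FPKM in the library labelled KIT against 2.95 and Cd8a at 10.2 against 0.777. Endothelial genes had a median of 1.02 (percentile 72.2), with Tek at 46.6 FPKM in the library labelled KIT against 3.47 and Cldn5 at 14.4 against 0.762. Mast cell and erythroid lists had 4 and 3 usable members and no percentile. With the library labelled KIT first, Gata2 was at 17.5 against 1.97 FPKM and Cpa3 at 3.03 against a listed 0, and the red-cell genes Alas2 and Slc4a1 were at 43.5 against 11.0 and 24.2 against 1.29 FPKM.

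Oxidative phosphorylation genes were mostly higher in the library labelled THY1, while a smaller share of glycolysis genes was. Of 24 oxidative phosphorylation genes, 20 were at least 2-fold higher there and 1 in the library labelled KIT, with a median of -4.31 below all random lists. Cox4i1 (985 FPKM), Ndufa1 (632), Uqcrc1 (449) and Ndufb5 (308) were listed at 0 in the library labelled KIT, as were 12 of the 25 measured members in all. Over the 13 genes above 0 in both libraries the median was -2.74 (percentile 0.355). Glycolysis had 11 of 20 genes higher in the library labelled THY1 and 6 in the other (median -1.75, percentile 1.56). Higher in the library labelled THY1 were hexokinase Hk1 at 773 against 11.6 FPKM, Aldoa at 613 against 28.8 and Gpi1 at 140 against 2.40. Chosen after its value was seen, Slc16a3 went the other way, at 402 FPKM in the library labelled KIT against 46.3. The 6 also held Gapdh, Eno1 and Pgk1, singled out after their values were seen. They were at 3.12, 1.96 and 1.87 FPKM in the library labelled KIT and listed at 0 in the other. Values this low may rest on few fragments, so the smaller share for glycolysis is uncertain. The retinoic acid list had 10 of 17 genes higher in the library labelled THY1 and 6 in the other (median -2.39, percentile 1.56). Its retinaldehyde dehydrogenases Aldh1a1 and Aldh1a2 were at 847 against 1.37 and 100.4 against 1.44 FPKM in favour of the library labelled THY1, while Lrat, which esterifies retinol, and the retinoic-acid-degrading Cyp26c1 were at 202 against 8.75 and 50.3 against 0.805 FPKM in favour of the library labelled KIT. Both the glycolysis and the retinoic acid list lay inside the random range with a pseudocount of 0.1, after scaling to the upper quartile or to the sum without Rpph1, and with no filter. Glycolysis also did so against unmatched random lists, and retinoic acid with a minimum of 5 FPKM or without genes listed at 0.

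Both lists above the random range, higher in the library labelled KIT, hold genes with near-identical copies, so their values are uncertain. Of 25 usable replication-dependent histone genes, 19 were at least 2-fold higher in the library labelled KIT and 4 in the other (median 2.23, percentile 99.94), such as Hist2h2ab at 339 against 35.9 FPKM, Hist2h2ac at 172 against 19.0 and Hist1h3a at 164 against 1.71. Of 53 cytosolic ribosomal protein genes, 32 were higher in the library labelled KIT and 17 in the other (median 1.63, percentile 99.85), and 22 of the 76 measured were listed at 0 in both. Rpl26 was at 51.8 FPKM in the library labelled KIT against 0.687. With no filter on low values both medians were 0, and without genes listed at 0 the ribosomal list lay at percentile 95.5. Of 444 usable X-linked genes, 279 were at least 2-fold higher in the library labelled THY1 and 99 in the other (median -1.69, below all random lists), and 445 of 727 measured were listed at 0 in the library labelled KIT against 243 in the other. Over the 224 usable X-linked genes above 0 in both libraries the median was -0.29, again below all random lists. Akap4, a sperm tail anchor protein, was at 544 FPKM in the library labelled THY1 against 14.3, and Tmsb15a (486 FPKM) was listed at 0 in the library labelled KIT.

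Cell cycle, replication and chromatin lists lay inside the random range. For the mitotic cell cycle, 15 of 24 genes were at least 2-fold higher in the library labelled THY1 and none in the other on the log2(FPKM + 1) scale (median -1.80, percentile 5.84), with Top2a at 116 FPKM in the library labelled THY1 against 1.35 and Bub1 at 71.5 against 1.63, while Ccna2 was at 96.6 FPKM in the library labelled KIT against 47.8. Without genes listed at 0 this list lay at percentile 1.83, outside the random range, as it also did with a minimum of 5 FPKM. DNA replication genes had a median of -0.86 (percentile 31.9), with Rrm1 at 55.8 FPKM in the library labelled THY1 against 0.667, and Ccne2 at 114 FPKM in the library labelled KIT against 16.5. DNA methylation genes had a median of -1.61 (percentile 16.4): Dnmt1, the maintenance methyltransferase, was at 39.4 FPKM in the library labelled THY1 against 15.7, Dnmt3a at 11.3 against 1.72, and Dnmt3b at 6.86 against a listed 0. Polycomb and Trithorax genes had a median of -1.20 (percentile 16.9), with Eed at 95.9 FPKM in the library labelled THY1 against 5.67 and Kdm5a at 28.8 against 0.582, while Kdm1a, a histone demethylase, was at 213 FPKM in the library labelled KIT against 89.9.

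Signalling and pluripotency lists also lay inside the random range, and pairs of values for their genes are given with the library labelled KIT first. Core pluripotency genes had a median of 1.85 (percentile 94.6), with 8 of 11 usable genes higher in the library labelled KIT and 2 in the other. At least 1 FPKM was reached by 10 members in the library labelled KIT and by 4 in the other. That minimum is easier to pass in the library labelled KIT, where 1 fragment is worth more, so these counts favour it. The same limit holds for the Wnt and Hox genes below (26 against 17 and 8 against 3 members). Klf2 was at 8.72 against 0.330 FPKM, Klf5 at 6.12 against a listed 0, and Stat3 at 9.03 against 54.0. Chosen after their values were seen, Pou5f1 was at 2.60 FPKM in the library labelled KIT and listed at 0 in the other, and Sox2 was listed at 0 in both. A value as low as that of Pou5f1 may rest on few fragments in the library labelled KIT. Wnt genes had a median of 1.10 (percentile 88.3), with 15 of 30 higher in the library labelled KIT and 6 in the other (percentile 97.9 without genes listed at 0). Lef1 was at 206 against 22.8 FPKM, Lgr5 at 69.7 against 4.48 and Wnt4 at 36.3 against 0.265. Axin1, at 0.781 against 23.1 FPKM, and Ctnnb1, at 31.4 against 93.0, went the other way. Hedgehog and Notch genes had a median of 1.21 (percentile 91.4), including Hes5 at 52.7 against 1.13 FPKM, Dll1 at 42.0 against 1.70 and Sufu at 3.20 against 72.9. GDNF and FGF genes had a median of -0.22 (percentile 41.4), with Etv4 at 46.1 against 1.59 FPKM and Dusp4 at 33.6 against 2.81. In the other direction, Spred1 and Fgfr2 were at a listed 0 against 22.2 and 15.3 FPKM. BMP and TGF-beta genes had a median of -0.31 (percentile 35.9), with Nodal at 28.3 against 1.30 FPKM and Smad2 at a listed 0 against 35.5. Hox genes had a median of 0.98 (percentile 64.4), and 15 of 33 were listed at 0 in both libraries, while Hoxb7 was at 13.0 FPKM in the library labelled KIT. Immediate early genes, which respond to cell dissociation, had a median of 0.42 (percentile 73.4), with Jund at 137 against 8.54 FPKM and Fos at 4.08 against 98.7.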

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

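The count of genes differing at least 2-fold (12555) stayed within 1.5 times under a pseudocount of 0.1, all 3 rescalings, no filter, a minimum of 5 FPKM and genes above 0 in both libraries. With a minimum of 30 FPKM it was 4990, since 5633 genes were then considered. That minimum, the scaling to the sum without Rpph1 and the restriction to genes above 0 in both were chosen after seeing the data. Rescaling shifted the median difference of all genes from -0.0026 to -0.046 (median ratio), 0.52 (upper quartile) and 0.21 (sum without Rpph1). Pearson's r across genes was 0.42, and became 0.49 with a pseudocount of 0.1, 0.15 among genes with a larger value of at least 1 FPKM and 0.25 among genes above 0 in both, where genes low or at 0 drop out, and the cause of the first was not tested. The number of lists outside the random range was 13, and 8 with no filter, where glycolysis, peritubular, retinoic acid, ribosomal and histone lists lay inside. The ribosomal and histone medians were then 0 (1.63 and 2.23 with the filter), since members listed at 0 in both entered. Without genes listed at 0 the median of the differentiating list turned from -1.92 to 0.082, as 5 genes were left. The other alternatives gave 10 to 13 lists. No named gene at least 2-fold apart changed direction under the pseudocount or scaling to the median ratio or upper quartile. The choice between rows of 1 symbol could not be tried, as no symbol was on several rows. No paired analysis was possible because each group analysed holds 1 library, and their titles carry no replicate number. Depth limits genes near 1 fragment, above all in the library labelled KIT.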

Other observations

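Gene families grouped by the start of their symbols, a survey chosen after the data were seen, gave 56 families with at least 20 usable genes. Of these, 11 lay below the central 95% of 2000 random lists and 9 above it, against 2.8 expected outside if genes were independent. Those below, which are higher in the library labelled THY1 (whose value column is headed Kit), included 6 given here. Translation initiation factors (Eif) had a median difference of -2.29, labelled KIT minus labelled THY1, with 37 of 55 genes at least 2-fold higher in the library labelled THY1 and 10 in the other. Eif3k (456 FPKM), Eif1ax (308 FPKM) and Eif3i (111 FPKM) were listed at 0 in the library labelled KIT. Mediator subunits (Med) had a median of -2.30, RNA helicases (Ddx) -2.18, kinesins (Kif) -2.11, WD-repeat genes (Wdr) -1.90 and mitochondrial ribosomal proteins (Mrpl) -1.88. Among families inside the random range were Atp (percentile 4.2), Polr (4.45), Taf (5.15), Vps (11.2), Cox (32.5) and the cytosolic ribosomal Rps family (median 0.88, percentile 87.1). The cytosolic ribosomal Rpl family (median 1.66) and histones (2.34) lay above that range.

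Families above the random range, higher in the library labelled KIT (whose value column is headed Thy1), included receptors. Of 1090 olfactory receptor genes (Olfr), 848 were listed at 0 in the library labelled KIT and 906 in the other, so the median gene was at 0 in both. Among the 252 with a larger value of at least 1 FPKM, 241 were at least 2-fold higher in the library labelled KIT and 10 in the other (median 2.94). That minimum is easier to pass in the library labelled KIT, where 1 fragment is worth more, so these counts favour it. The same limit holds for vomeronasal receptors (Vmn), with 50 of 57 usable genes of 292 higher there (median 2.08), and for orphan G-protein-coupled receptors (Gpr), with 51 of 64 usable genes of 96 (median 2.05). Gpr15 was at 158 FPKM in the library labelled KIT against 6.91, while Gpr108 was at 1.54 against 65.6. Solute carriers (Slc) and zinc-finger genes (Zfp) had medians of 0.86 and 0.95.

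Of the tests of the 3 patterns below, those of exchanged titles, of even genomic fragments, of short transcripts and of fewer germ cells were chosen after the result was seen. All intervals of resampled genes describe these 2 libraries and are not replicate error.

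Kit and Thy1 ran opposite to the sample titles. Exchanged titles stay open: the column headings name the other antigen, and the stem-cell-associated median exceeded the differentiating median by 2.96, at percentile 98.7 of 10000 random pairs of matched lists. Both medians were known before that difference was taken, so it is no independent support, and it rests partly on genes listed at 0, because the differentiating median was 0.082 over the 5 genes above 0 in both. A missed Kit value in the library labelled KIT stays open, since 154 of 1356 genes (11.4%, exact interval 9.72 to 13.2) of like length and like value in the library labelled THY1 were listed at 0 there. Other cells also stay open as sources, T lymphocytes for Thy1 (list median 1.58, percentile 91.8, with Cd5 at 27.5 and Cd8a at 10.2 FPKM in the library labelled KIT) and Leydig cells, which are known to carry KIT, for Kit.

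Sensory receptor genes (olfactory, vomeronasal and taste), best known from sensory tissue, reached at least 1 FPKM for 310 of 1414 genes (21.9%) in the library labelled KIT and for 119 (8.42%) in the library labelled THY1, and at least 10 FPKM for 159 and 15. Fragments drawn evenly from the genome, without repeated amplification, are argued against as the whole source, since the variance over mean of fragments per receptor gene above 0, set against length, was 243.8 (149.5 to 323.5), or 48.8 if 1 fragment is worth 5 times as much. Low depth alone is argued against by 79.5% of the receptor genes above 0 lying at 5 or more times the worth of 1 fragment (exact interval 74.6 to 83.8). That share was 39.7% if each is taken as 1000 bases long. A preference for short transcripts stays open. The ratio of the shares at 10 FPKM or more between the libraries was 13.4 times that of other genes of the same length (8.81 to 24.7). These other genes were not matched on level, with 29.2% and 37.0% at 10 FPKM or more (labelled KIT first). Receptor genes stood at 11.2% and 1.06%, so a difference among low genes of any length could give that ratio. Genomic DNA from male cells as a part of the library may still contribute, because X-linked genes had 0.447 of the mean FPKM of autosomal genes of the same length (0.314 to 0.608) among genes above 0 and below 1 FPKM in the library labelled THY1. Lower transcription from the single X chromosome would give the same value, and strong amplification of few molecules was not tested, so both stay open, as does a biological difference between the 2 cell fractions. A genomic part could also raise genes outside the receptor families, Nanos2 and other stem-cell-associated genes included, which was not tested.

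Leydig cell genes were high in the library labelled THY1, among them Ptgds (6463 FPKM), Cyp17a1 (2945 FPKM) and Cyp11a1 (2272 FPKM). RNA of Leydig cells is a candidate source: 12 other genes known from Leydig cells, none of them in another list and chosen before their values were seen, had a median difference of -5.03, below all random lists, with 10 higher in the library labelled THY1 and 2 in the other. Among them Apoe was at 726 FPKM in the library labelled THY1 against 50.9, Acsbg1 at 299 against 4.37 and Klk1b27, which has near-identical copies, at 561 against a listed 0, while Tspo was at 14.9 against 65.9, and over the 6 above 0 in both libraries the median was -3.91 (percentile 0.52). Whether that library held fewer germ cells cannot be decided. The 140 usable genes of the 7 germ cell lists had a median difference of -2.16 (-2.66 to -1.35). Over the 98 above 0 in both libraries it was -1.29 (-2.16 to -0.24). Of the 140, 90 were at least 2-fold higher in the library labelled THY1 and 34 in the other. The list medians were known before they were pooled, so this is no independent support. Relative values also do not measure the number of germ cells. The gap of the Leydig median to that of endothelial genes was -5.14 (-9.18 to -0.85) and to that of peritubular genes -2.39 (-8.19 to 1.83). Without genes listed at 0 these gaps were -4.14 (-7.96 to -1.45) and -1.02 (-6.35 to 2.36). The interval for macrophages (-8.10 to 0.08) also held 0. That for Sertoli genes excluded 0 as deposited (-8.08 to -0.32) and after upper quartile scaling (-7.99 to -0.19), and held 0 without genes listed at 0 (-6.76 to 0.19). Higher values shared with peritubular cells, macrophages and, less clearly, Sertoli cells stay open. Expression in the germ cells themselves was not tested and also stays open.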
